A study of Mus musculus with 12 samples.

How the data were processed

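RNA was sequenced from the renal cortex of mice in 4 groups of 3 libraries each. Per the labels, the groups were wild-type sham (WT sham), knockout sham (CKO sham), wild-type after ischemia-reperfusion injury (WT IRI) and knockout after the same injury (CKO IRI). The knocked-out gene was Gpx3, deleted in the tubular epithelium, and injury was 30 min of bilateral renal ischemia with 48 h of reperfusion, per the series design text. Per the labels' protocols, total RNA was fragmented, primed at random and made into strand-marked libraries with dUTP in the second strand. The labels' extraction protocol speaks of joint capsule, while their tissue field and the design text say kidney. Nothing in the labels says how the animals were paired, and nothing states that each library was a separate animal, so p-values measure the spread between these libraries.

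The authors deposited 1 table of 25790 mouse transcripts by 12 libraries, read here as FPKM. Per the submitters' processing notes, cutadapt, HISAT2 2.1.0 and StringTie were used. The header does not name the unit, and StringTie can also write TPM, which would differ from FPKM by 1 factor per library. The notes name a human genome build (GRCh38), whereas the transcript identifiers are mouse. No strand setting, annotation release or depth was given in the sources used here. In each row of the deposited FPKM table the mean of at least 1 of the 4 groups was 0.5 or more, so transcripts below that level were not analysed here. All 12 columns were used.

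Transcript identifiers were matched without their version suffix to GENCODE M21 (mouse build GRCm38), which gave 25740 matches. The 50 unmatched transcripts held at most 0.10% of the summed values of any library and were left out. Values were summed per gene, which gave 13465 genes. Coordinates in the text are those of that annotation. Near-identical gene copies and overlapping genes can share reads in ways the table does not show.

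Summed values per library lay between 391002 and 422328 FPKM. The number of reads behind them is unknown. In genes with 1 deposited transcript, the low values multiplied by transcript length showed faint steps, but only 24.1% to 38.5% of them lay within 0.1 of a whole multiple, where chance gives 20.0%. Whole reads were therefore not recovered, no count test was run, and no interval for counting error is given. Exact zeros occurred in some library for 6211 transcripts, including a Gapdh transcript, so a zero is reported only as a value listed at 0.

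Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 12469 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with 1 mean per group, a mean-variance trend and 1 spread shared by the 4 groups. Log2 changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 within each of 5 contrasts: IRI against sham in each genotype, CKO against WT in sham and after IRI, and the genotype by IRI interaction. Tests were two-sided.

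Gene lists were fixed before the data were examined, 44 in number, and 43 had tested members. They covered nephron segments, injury, metabolism, stress, inflammation, other cell types and other tissues. Each was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a contrast. Camera with an estimated correlation and fry were alternatives. Named genes followed a rule fixed at the same time. They were Gpx3, the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap between the groups (predicted or clone names left out), and up to 4 members with the smallest p in each described list. Where fewer than 4 genes passed, the 4 of smallest p in each direction were named. Described lists were tubular injury, proximal tubule, antioxidant enzymes and each list that camera called. Some genes that the rule selects are not reported here.

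The model was tested on simulated data, with 200 of the 12469 genes changed and each group given its own spread. In the simulated CKO against WT comparison in sham, changes of 0.5, 1, 2 and 3 (log2) were recovered in 8%, 38%, 78% and 100% of 50 genes each, and 1 of 113 calls was false. A fit of only the sham groups recovered 123 of the 200 changed genes, against 112 with the shared spread, and 6 of its 129 calls were false. In the comparison after IRI, 20%, 50%, 94% and 100% were recovered, but 36 of 168 calls (21.4%) were false. With a fit of only the groups compared, 7 of 106 calls (6.6%) were false there, and with array weights 8 of 124 (6.5%). These fits recovered 99 and 116 of the 200 changed genes, against 132 with the shared spread. In IRI against sham in WT, 18%, 66%, 88% and 98% were recovered and 11 of 146 calls (7.5%) were false. The shared spread, fixed before the data were examined, was thus too liberal after IRI, where replicate spread was largest. A list shifted by 0.5 was called in the simulated sham comparison and 0 of the others were, of 43 tested. Genes were simulated independently of each other, so this does not test the list calls where genes are correlated.

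Alternatives were other pseudocounts (0.1 and 0.5), no filter and a filter of 5 FPKM, trimmed-mean scaling, quantile normalization, a fit of only the groups compared, array weights, robust empirical Bayes, no trend, a threshold of 1 on the log2 change, and leaving out each library in turn. For the sham groups the replicate number was also entered as a block. Alternatives chosen after seeing the data were a test of single transcripts, genes with no transcript at 0, 1 weight per group, and leaving out CKO sham 1 and WT IRI 49 together. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.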

Results

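Bulk RNA sequencing profiled the renal cortex of mice with or without Gpx3, the gene of the secreted glutathione peroxidase, in tubular epithelial cells. Each genotype was sampled after sham surgery or after 30 min of bilateral ischemia and 48 h of reperfusion, with 3 libraries in each of the 4 groups. The series asks how tubular Gpx3 affects renal gene expression during acute injury. Libraries summed to between 391002 and 422328 FPKM, and their read depth is unknown. WT sham libraries varied least, with a median SD of 0.10 (log2) per gene, against 0.17 in CKO sham, 0.27 in WT IRI and 0.23 in CKO IRI. Correlations across genes between replicate libraries were 0.984 in WT sham, 0.962 to 0.982 in CKO sham, 0.921 to 0.945 in WT IRI and 0.935 to 0.961 in CKO IRI, and no libraries were identical. The first principal component held 53.7% of the variance and placed CKO IRI 15 at 2.3 and WT IRI 13 at 72.5, with the sham libraries between -38.6 and -25.7.

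The targeted gene was examined first, as a check of the labels. Gpx3 lies on chromosome 11 (54902453 to 54910377, plus strand, GRCm38), and its value here is the sum of 3 deposited transcripts. It measured 5664, 4476 and 5371 FPKM in WT sham 1, 2 and 3, and 2501, 3037 and 3299 FPKM in CKO sham 1, 2 and 3. CKO sham libraries therefore averaged 2946 ± 407 FPKM (SD, n = 3), below each of the WT sham libraries, which averaged 5170 ± 619 FPKM (SD, n = 3). The difference was -0.81 (log2, SE 0.36), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, and a limma adjusted p of 0.755. That adjusted p was 0.232 with only the sham groups fitted and 0.0918 with array weights. WT IRI 49 enters this comparison only through the shared spread and the choice of tested genes. Without that library the SE was 0.18 and the limma p 0.00095 unadjusted and 0.417 adjusted. After injury the order was not kept. The libraries labelled WT IRI 13, 24 and 49 held 2788, 3568 and 1075 FPKM, and those labelled CKO IRI 7, 15 and 29 held 3723, 3025 and 2779 FPKM. The group means were 2477 ± 1275 and 3176 ± 490 FPKM (SD, n = 3 each), a difference of 0.52 (log2, SE 0.36, limma adjusted p = 0.421, exact permutation p = 0.5). Without WT IRI 49 it was -0.001. Gpx3 thus did not separate the genotype labels after IRI, so directions between genotypes there are written for libraries as labelled. Which part of the gene was deleted is not given in the sources used here, and reads from outside a deleted part would not report the deletion.

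**Figure D1:**
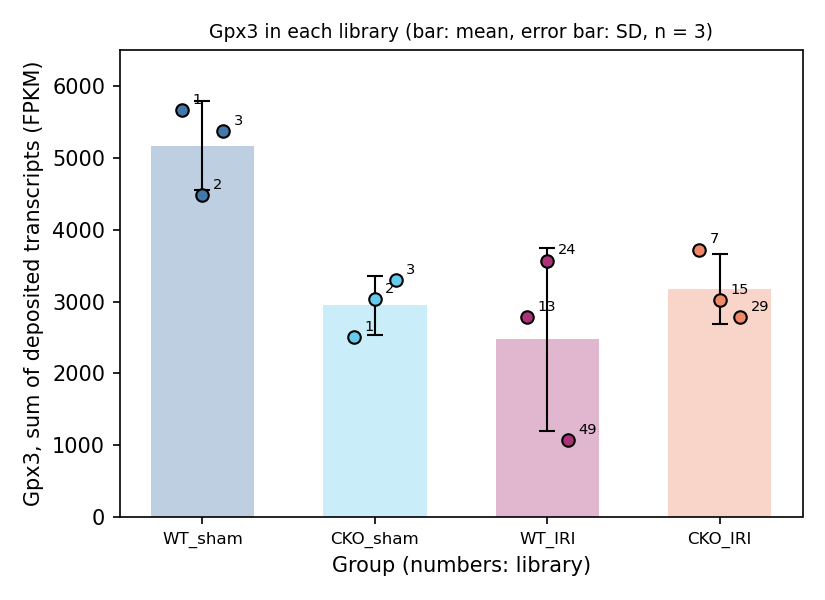
Gpx3 in each of the 12 libraries, as summed FPKM of its deposited transcripts (vertical axis) by group (horizontal axis), with bars for means, error bars for SD (n = 3) and the library number beside each point. The CKO sham libraries (2501 to 3299) lie below the WT sham libraries (4476 to 5664), whereas the libraries labelled WT IRI (1075 to 3568) and CKO IRI (2779 to 3723) overlap.

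Ischemia-reperfusion injury in kidneys labelled WT raised tubular injury and cell cycle genes and lowered proximal tubule genes. Havcr1, which encodes kidney injury molecule 1, rose from 1.71 ± 1.45 to 331 FPKM (276 to 370 in the 3 libraries; limma log2 change 7.05, SE 0.49, adjusted p = 6.73e-06). Krt20, a keratin, and Lcn2, the lipocalin NGAL, rose by 5.95 and 5.57 (log2), to 98.3 ± 62.9 and 324 ± 163 FPKM. The other leading rises were Birc5 (5.07), S100a6 (4.93), Sprr1a (4.62), Ccnb2 (4.55) and Akr1b8 (4.54). The leading falls were the organic anion transporter Slc22a7 (-5.41), the histidine decarboxylase Hdc (-4.81), Cyp2a4 (-4.46), Slc22a19 (-4.41) and Akr1c14 (-4.20). Slc7a12 (-4.52), Mep1b (-4.18) and Akr1c18 (-4.16) also fell, but passed the threshold neither without WT IRI 13 (adjusted p 0.0681, 0.0701 and 0.0557) nor without WT IRI 24 (0.0593, 0.0644 and 0.0534). Slc7a12 and Mep1b also did not pass without WT sham 2 (0.0505 and 0.0534), nor Mep1b without WT sham 3 (0.0508).

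Of 30 tested tubular injury genes, 29 rose and none fell, and 30 rose adjusted over the list alone. Of 40 cell cycle genes 38 rose (39 adjusted over the list alone), including the proliferation marker Mki67, from 0.51 ± 0.05 to 19.0 ± 2.50 FPKM, Ube2c (4.23), Aurka (3.62) and Cdc20 (4.54). Of 45 proximal tubule genes 36 fell and none rose (37 adjusted over the list alone). They included the phosphate transporter Slc17a3 (-1.88), Keg1 (-1.21), Spp2 (-1.29) and Lrp2, the endocytic receptor megalin, which went from 178 ± 7.12 to 50.5 ± 23.7 FPKM. Among fatty acid oxidation and peroxisome genes 22 of 41 fell and 1 rose (25 and 1 adjusted over the list alone), with Ehhadh at -2.24 and Acadm, the medium-chain acyl-CoA dehydrogenase, at -2.08, and none rose without WT sham 1, 2 or 3, WT IRI 24 or WT IRI 49. Gluconeogenesis genes fell in 4 of 8 (4 adjusted over the list alone), Pcx by -1.72 and Fbp1 by -1.83. Cholesterol synthesis genes fell in 6 of 20 and rose in 1 (6 and 1 adjusted over the list alone), with Cyp51 at -2.21. Only 2 fell without WT IRI 13 or WT IRI 24 and 3 without WT sham 1 or WT sham 3, and none rose without WT IRI 13, WT IRI 24, WT IRI 49, WT sham 2 or WT sham 3. Of 46 ribosomal protein genes 43 rose (45 adjusted over the list alone), by a median of 0.83, Rpl10a by 1.02 and Rps16 by 1.14.

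Inflammatory and stromal genes rose as well. Of 31 NF-kB and cytokine genes 22 rose (23 adjusted over the list alone), with the smallest p for Osmr (1.86), Socs3 (3.42) and Ccl20 (2.69). Of 30 fibroblast and extracellular matrix genes 21 rose (24 adjusted over the list alone), with Col1a1 going from 3.55 ± 0.42 to 79.6 ± 46.8 FPKM, Col3a1 up by 3.58 and Vim by 3.29. Of 28 macrophage and monocyte markers 13 rose (14 adjusted over the list alone), Cd14 by 2.56 and Tyrobp by 1.13, and of 22 p53 and DNA damage response genes 12 rose (13 up and 1 down adjusted over the list alone), Gdf15 by 2.58 and Bbc3 by 1.74. Loop of Henle and distal nephron genes fell in 9 of 20 (9 adjusted over the list alone), including Slc8a1 (-2.25) and Wnk1 (-1.21), but in 4 without WT IRI 13 and in 5 without WT IRI 24 or WT sham 3. Podocyte markers fell in 4 of 14 (4 adjusted over the list alone), though without WT IRI 24 3 fell and 2 rose, and endothelial markers in 5 of 18 with 1 rise (4 and 1 adjusted over the list alone), Kdr by -1.65. Endothelial falls numbered 3 without WT IRI 13, 2 without WT sham 1 or WT sham 2 and 1 without WT IRI 24 or WT sham 3, and rises 0 without WT sham 1 and 2 without WT IRI 49. Of 75 nuclear oxidative phosphorylation genes 6 fell and 1 rose (5 and 0 adjusted over the list alone), with Ndufs1 at -1.56 and a list median of -0.09 (-0.01 without WT IRI 24, -0.15 without WT IRI 49 and -0.05 without WT sham 2), and 12 fell without WT IRI 49. Rises in that list numbered 3 without WT IRI 24 and 0 without WT sham 1, 2 or 3 or WT IRI 13. Of 13 mitochondrial genome genes 1 passed (0 adjusted over the list alone), mt-Nd6 at -0.63, which did not pass without WT sham 1 (adjusted p 0.0761), WT sham 2 (0.148), WT sham 3 (0.0613) or WT IRI 24 (0.139), nor when only these groups were fitted (0.0849), while 7 others fell without WT IRI 24. Without WT IRI 49 a gene fell in each of the fibroblast, macrophage and p53 lists. The median of the mitochondrial genome list was -0.57, and -0.18 without WT IRI 13, in which mitochondrial transcripts made up 3.9% of the summed values. In the glutathione S-transferase and conjugation list 9 of 29 fell and 4 rose (10 and 5 adjusted over the list alone), Dpep1 by -1.59 and Gstp2 by 1.33, and 5 fell without WT IRI 13.

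Antioxidant enzymes moved in both directions. Of 33 tested members 5 rose and 7 fell (5 and 7 adjusted over the list alone), and camera did not call the list (adjusted p = 0.209). Without WT sham 3, 4 fell. Gpx7 rose by 1.67 and Prdx4 by 0.94, whereas the mitochondrial superoxide dismutase Sod2 changed by -0.90 and catalase (Cat) by -1.11, from 367 ± 8.28 to 174 ± 47.4 FPKM. Gpx3 itself fell by 1.22 (adjusted p = 0.0221), or by 0.71 without WT IRI 49, though not past the threshold without WT sham 1 (0.0679), without WT sham 3 (0.0635), after quantile normalization (0.0727) or when only these groups were fitted (0.0773).

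In all, limma called 3125 genes up and 1483 down of 12469, and camera called 17 of 43 lists (7 up, 10 down). None of the list calls held with an estimated correlation (lowest adjusted p = 0.496). Another division of the same 6 libraries also gave 17 list calls. Its sides held unequal numbers of IRI libraries, so part of the injury difference stayed in it, and it does not measure chance alone. With quantile normalization the split was 2205 up and 2172 down, and with trimmed-mean scaling 2365 and 2098, since these settings moved the median change of all genes from 0.12 to -0.03 and 0.01. Camera no longer called the mitochondrial genome, gluconeogenesis, nuclear oxidative phosphorylation, glutathione conjugation and endothelial lists after quantile normalization, the nuclear oxidative phosphorylation, podocyte and endothelial lists without WT IRI 24 (adjusted p 0.261, 0.0651 and 0.186), or the macrophage and monocyte list without WT IRI 49 (0.0776).

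The same injury in kidneys labelled CKO raised tubular injury and cell cycle genes. Havcr1 rose from 2.14 ± 0.79 to 242 ± 159 FPKM (SD, n = 3 each; limma log2 change 6.06, SE 0.49, adjusted p = 4.03e-05), Krt20 by 4.86 and Lcn2 by 4.49. The other leading rises were the cell cycle genes Ccnb2 (3.83), Birc5 (3.82), Rrm2 (3.76), Cdc20 (3.58) and Ccna2 (3.57). The leading falls were Sec14l3 (-2.92), Akr1c14 (-2.74), the clock-controlled transcription factor Dbp (-2.59), the fatty acid desaturase Scd1 (-2.56), Slc22a26 (-2.52), Prok1 (-2.48), the clock repressor Nr1d1 (-2.47) and the endothelial gene Esm1 (-2.37). Of these, Sec14l3, Akr1c14, Scd1 and Slc22a26 did not pass without CKO sham 1 (adjusted p 0.0977, 0.116, 0.056 and 0.126), without CKO sham 2 (0.114, 0.142, 0.125 and 0.144), without CKO IRI 7 (0.11, 0.102, 0.107 and 0.105) or without CKO IRI 29 (0.122, 0.139, 0.131 and 0.156). Without CKO sham 3, Sec14l3, Akr1c14 and Scd1 did not pass (0.0662, 0.0875 and 0.11), and none of the 4 passed when only these groups were fitted (0.0530 to 0.0954). Sec14l3, Akr1c14 and Slc22a26 did not pass with a pseudocount of 0.1 (0.0726, 0.0907 and 0.0853), nor Akr1c14 and Slc22a26 with 0.5 (0.0636 and 0.0580), nor these 3 without CKO sham 1 and WT IRI 49 together (0.0783, 0.0562 and 0.0726), a setting chosen after seeing the data.

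By list, 37 of 40 cell cycle genes rose (39 adjusted over the list alone), Mki67 from 0.70 ± 0.10 to 12.6 ± 2.95 FPKM and Top2a by 3.29. Tubular injury genes rose in 18 of 30 (29 adjusted over the list alone), among them S100a6 by 3.22. Of 45 proximal tubule genes 4 fell (12 down and 2 up adjusted over the list alone), including Spp2 (-1.21), the glucose transporter Slc5a2 (-1.06) and Keg1 (-0.89). Fibroblast and extracellular matrix genes rose in 9 of 30 (18 adjusted over the list alone), Lox by 1.69 and Col1a1 by 2.77, and NF-kB and cytokine genes in 7 of 31 (13 up and 2 down adjusted over the list alone), Osmr by 1.25 and Cxcl1 by 2.94. Gdf15 (1.78) and Cdkn1a (2.66) were among the 3 of 22 p53 and DNA damage response genes that rose (5 adjusted over the list alone). Interferon response genes fell in 4 of 31 (4 adjusted over the list alone), Iigp1 by -1.63. MHC class II genes fell in 3 of 6 (4 adjusted over the list alone) and endothelial markers in 3 of 18 (11 adjusted over the list alone). The examples Cd74 (-1.40) and Kdr (-1.32) passed neither without CKO sham 1 (adjusted p 0.0866 and 0.0639), without CKO sham 2 (0.083 and 0.0815) nor without CKO sham 3 (0.0697 and 0.0796), and Kdr did not pass without CKO IRI 7 (0.083). The change of Cd74 was -0.92 without CKO IRI 29. Medians of the interferon response, MHC class II and endothelial lists were -0.37, -1.25 and -0.90 (adjusted p with an estimated correlation 0.402 each), and -0.21 without CKO sham 1, -0.81 without CKO IRI 29 and -0.56 without CKO IRI 7. Cxcl1 and Cd74 did not pass when only these groups were fitted (0.0567 and 0.112), nor Cd74 without CKO sham 1 and WT IRI 49 together (0.0767). In the glutathione S-transferase and conjugation list 3 of 29 fell (4 down and 2 up adjusted over the list alone), and in the ribosomal list 2 of 46 rose (2 adjusted over the list alone). Many of these counts over all genes rested on single libraries. MHC class II falls numbered 0 without CKO sham 1, 2 or 3 and 1 without CKO IRI 7 or 29. Interferon response falls numbered 1 without CKO sham 1, 2 or 3 or CKO IRI 7, and 2 without CKO IRI 29. Endothelial falls numbered 0 without CKO sham 1, CKO sham 2 or CKO IRI 7, 1 without CKO sham 3 or CKO IRI 29, and 10 without CKO IRI 15. Glutathione conjugation falls numbered 0 without CKO sham 2, CKO sham 3 or CKO IRI 7, 1 without CKO sham 1 or CKO IRI 29, and 5 without CKO IRI 15, with 1 rise without CKO sham 1 or CKO IRI 15. Ribosomal rises numbered 0 without CKO sham 2, CKO sham 3, CKO IRI 7 or CKO IRI 29 and 1 without CKO sham 1. NF-kB and cytokine rises numbered 2 without CKO sham 2, CKO sham 3 or CKO IRI 7 and 3 without CKO IRI 29. Fibroblast and extracellular matrix rises numbered 3 without CKO sham 2, CKO sham 3 or CKO IRI 29, 4 without CKO IRI 7 and 5 without CKO sham 1. A proximal tubule gene rose without CKO sham 3 or CKO IRI 29. No member passed in the nuclear oxidative phosphorylation (75 tested, 4 lower without CKO IRI 15), mitochondrial genome (13), blood (5) and T and NK cell (2) lists, which camera called lower with medians of -0.19, -0.31, -2.16 and -0.92, while 2 T and NK cell genes were lower adjusted over the list alone. With an estimated correlation these calls were lost (adjusted p = 0.574, 0.574, 0.458 and 0.402). The median of nuclear oxidative phosphorylation was -0.07 without CKO IRI 29 and -0.33 without CKO IRI 15, that of the mitochondrial genome -0.21 without CKO IRI 29 (call lost, adjusted p 0.0596) and that of blood -1.37 without CKO IRI 7. The T and NK cell call was lost without CKO sham 1 (0.16), CKO IRI 15 (0.0636), WT sham 1 (0.11) or WT sham 2 (0.102); the WT libraries enter this comparison only through the shared variance and the choice of tested genes. Camera also called the podocyte list lower, with a median of -0.11 and an adjusted p of 0.502 with an estimated correlation. That call was lost without CKO sham 3 (0.126) or CKO IRI 7 (0.141), and the median was -0.28 without CKO sham 1, -0.18 without CKO sham 2, -0.21 without CKO IRI 15, -0.32 without CKO IRI 29 and -0.23 without WT sham 2. Of 33 antioxidant enzymes 1 rose (0 adjusted over the list alone), Gpx7 by 0.80. It did not pass without CKO sham 2 (adjusted p 0.159), CKO sham 3 (0.136), CKO IRI 7 (0.116) or CKO IRI 29 (0.155), nor with the filter of 5 FPKM (0.0573), either scaling (0.0619 and 0.0788) or only these groups fitted (0.0957), while without CKO IRI 15 3 antioxidant enzymes rose and 1 fell. Gpx3 changed by 0.11 (SE 0.36, adjusted p = 0.891).

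limma called 711 genes up and 185 down, and camera called 16 of 43 lists (6 up, 10 down), none of which held with an estimated correlation (lowest adjusted p = 0.2). Another division of the libraries gave 19 list calls, but its sides also held unequal numbers of IRI libraries. The glutathione conjugation call was lost without CKO IRI 7 (adjusted p 0.117), and the p53 and DNA damage response call without CKO sham 2 (0.068) or CKO IRI 7 (0.0517). The gene count was 476 when only these groups were fitted, 402 without CKO sham 2, 396 without CKO sham 3, 412 without CKO IRI 7, 485 without CKO IRI 29 and 1453 without CKO IRI 15, and the split was 514 up and 296 down with quantile normalization and 555 and 253 with trimmed-mean scaling.

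**Figure D2:**
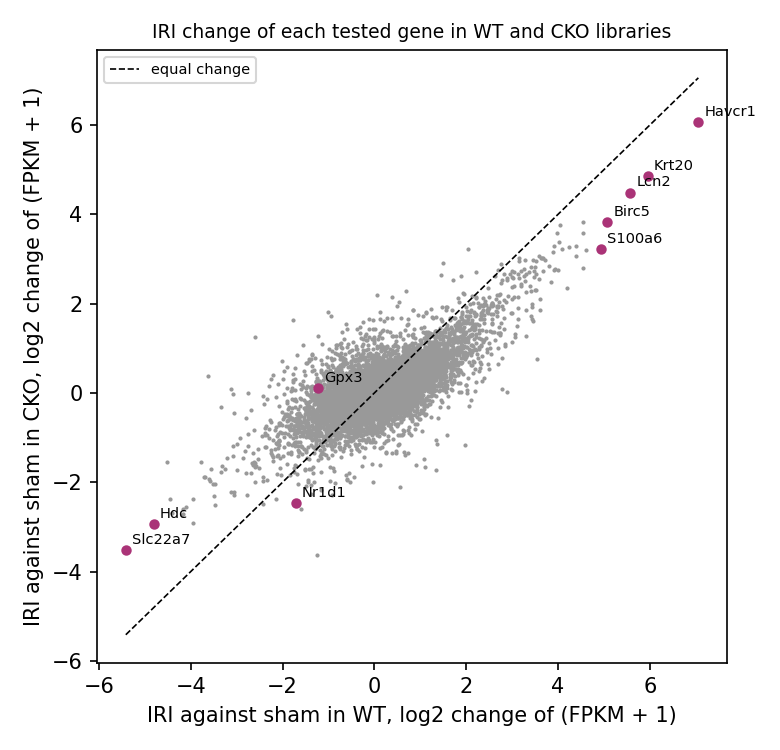
Log2 change of FPKM + 1 from sham to IRI for each of the 12469 tested genes, in WT libraries (horizontal axis) and CKO libraries (vertical axis), with a dashed line where both changes are equal. Havcr1, Krt20 and Lcn2 lie at the upper right (WT 7.05, 5.95 and 5.57, CKO 6.06, 4.86 and 4.49), below the line.

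The changes with injury were related between the genotypes. Across genes, which are not independent replicates, the log2 changes in WT and CKO had a Pearson r of 0.703 and a Spearman rho of 0.576, with a slope of 0.478 for CKO on WT. No library was shared between these comparisons. Of the 3125 genes up in WT and 711 up in CKO, 625 were up in both, against 178 expected from independent lists, and 123 were down in both, against 22 expected. Among the 4669 genes called for the mean of both changes, the median ratio of the CKO change to the WT change was 0.579, and 82.4% changed less in CKO. The test of the difference for single genes is the interaction below.

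Knockout and WT kidneys were compared without injury. Of the genes higher in CKO, those with the smallest p were Sfrp2, a secreted Wnt-binding protein (4.73 ± 0.64 against 1.09 ± 0.18 FPKM, SD, n = 3 each, limma adjusted p = 0.0605), Psmg1, Id3 and Btbd2 (log2 differences 0.86, 1.03 and 0.98). Of the lower ones they were the potassium channel Kcnk5 (-1.28), Errfi1 (-0.94), Mylip (-1.11) and Rap1gap2 (-1.19). None of these passed. No gene of 12469 was called by limma, while 816 had an unadjusted p under 0.05. With only the sham groups fitted 11 genes were called (7 up, 4 down), and with array weights 124. The count was 1 without WT sham 1, 1 without CKO sham 2 and 2 without CKO sham 1.

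Camera called 12 of 43 lists in the sham comparison, none of which held with an estimated correlation (lowest adjusted p = 0.809), and another division of the 6 sham libraries gave 14 calls. No member of any list passed, over all genes or adjusted over the list alone. Lists with higher values in CKO were ribosomal proteins (median 0.31, with Rps28 at 0.45), interferon response (0.48, Ifit1 at 1.02), nuclear oxidative phosphorylation (0.29, Ndufa3 at 0.51), macrophage and monocyte (0.27, Tyrobp at 0.74), mitochondrial genome (0.30, mt-Nd3 at 0.64), endothelium (0.27), NF-kB and cytokines (0.24), fibroblast and extracellular matrix (0.29) and liver (0.39). Those with lower values were fatty acid oxidation and peroxisome (-0.16, Hsd17b4 at -0.39), cholesterol synthesis (-0.21, Srebf2 at -0.39) and proximal tubule (-0.18, Cyp27b1 at -0.86). Tubular injury (0.23, adjusted p = 0.0542) and antioxidant enzymes (0.06, adjusted p = 0.294) were not called, and of the latter Prdx6 differed by -0.65. CKO sham 1 stood apart from the other sham libraries on the second principal component (-37 against -2.2 to 9.2). Without it the median of the proximal tubule list was -0.02 (camera adjusted p 0.704), and the calls of endothelium (0.132), NF-kB and cytokines (0.113), cholesterol synthesis (0.132) and fibroblast and extracellular matrix (0.202) were lost too, with medians of 0.19, 0.12, -0.14 and 0.17, while the macrophage and monocyte median was 0.18 and that of tubular injury 0.13. The proximal tubule, cholesterol synthesis, fibroblast and liver calls were also lost without WT sham 1 (0.0621 each), those of proximal tubule and liver without WT sham 3 (0.0528 each), that of fibroblast without CKO sham 3 (0.0608), and that of liver without WT sham 2 (0.0639), CKO sham 2 (0.0712), CKO sham 3 (0.0884), WT IRI 13 (0.0776) or WT IRI 49 (0.0506). Tubular injury was called without WT sham 3 (0.0371), CKO sham 3 (0.0445), WT IRI 49 (0.0225), CKO IRI 15 (0.046) or CKO IRI 29 (0.0152). Without CKO sham 3 the medians of endothelium and proximal tubule were 0.46 and -0.28. Mitochondrial transcripts made up 12.3% of the summed values of CKO sham 1, against 9.5% to 11.1% in the other sham libraries.

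After injury, limma called 5 genes between the libraries labelled CKO and WT. Tmem67, a ciliary membrane protein gene, was listed at 0, 0 and 0.09 FPKM in WT IRI 13, 24 and 49 and at 2.40, 2.23 and 2.15 FPKM in CKO IRI 7, 15 and 29 (log2 difference 1.66, SE 0.11, adjusted p = 8.84e-05). Pofut2, an O-fucosyltransferase gene, was lower in CKO-labelled libraries, at 9.27 ± 0.63 against 29.3 ± 2.05 FPKM (SD, n = 3 each; -1.56, SE 0.10, adjusted p = 8.84e-05). Crybg3 (1.17), the phosphodiesterase Pde4b (1.08) and Ankle1 (-1.57) were the others. None of the 5 passed when only these groups were fitted (Tmem67 and Pofut2 adjusted p = 0.0611, the others 0.397). On simulated data 7 of 106 calls of that fit were false, against 36 of 168 with the shared spread, but it recovered 99 of 200 changed genes, against 132. Array weights had 8 false of 124 there but called 723 genes here, so the simulation does not choose between these 2 fits. Pde4b did not pass without WT IRI 13 (0.0712), CKO IRI 7 (0.124) or CKO IRI 15 (0.0756), nor Ankle1 without WT IRI 13 (0.0826) or CKO IRI 15 (0.086) or after trimmed-mean scaling (0.0525) or quantile normalization (0.0782) or with a pseudocount of 0.1 (0.139) or 0.5 (0.0814). With 1 weight per group, a setting chosen after seeing the data, Crybg3 (0.0687), Pde4b (0.244) and Ankle1 (0.164) did not pass. Unadjusted p was under 0.05 for 2609 genes. Without WT IRI 49 the count was 1394, without WT IRI 24 it was 12, without CKO IRI 15 it was 8 and without CKO IRI 29 it was 41.

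Camera called 16 lists between the libraries labelled CKO IRI and WT IRI, 10 higher and 6 lower in CKO. None held with an estimated correlation (lowest adjusted p = 0.508), another division of these 6 libraries gave 17 calls, and no member of the lists passed over all genes. The calls of 7 lists were kept with any 1 of the 6 libraries left out. Of 41 fatty acid oxidation and peroxisome genes 28 were higher and 1 lower adjusted over the list alone, with Ehhadh at 149 ± 49.7 against 56.3 ± 7.55 FPKM (1.34), Acot12 at 0.97 and Cyp4a10 at 1.49. The list means of each CKO IRI library (6.02 to 6.31, log2) exceeded those of each WT IRI library (5.40 to 5.85), with an exact permutation p of 0.1, the smallest possible for n = 3 against 3. Among the 43 lists, gluconeogenesis, NF-kB and cytokines, cell cycle, ferroptosis and apoptosis regulators reached the same p. Such a separation was thus not particular to the fatty acid list. Proximal tubule genes had a median difference of 0.64, Slc17a3 of 1.03 and the gluconeogenic enzyme Pck1 of 1.02, and 2 of 45 passed adjusted over the list alone, but the library means overlapped (exact permutation p = 0.2). Gluconeogenesis (0.75, and 0.47 without CKO IRI 7; 5 of 8 higher adjusted over the list alone) and the mitochondrial genome (0.62, and 0.15 without WT IRI 13) were the other higher lists of these. Lower were NF-kB and cytokines (median -0.67, 10 of 31 lower adjusted over the list alone, Relb at -1.15 and Nfkb2 at -0.95), cell cycle (-0.43, and -0.23 without CKO IRI 15, with Birc5 at -1.02) and ribosomal proteins (-0.31). The other 9 calls were each lost without at least 1 library. Without CKO IRI 15 these were tubular injury (median -0.72, and -0.31 without it, adjusted p 0.353), loop of Henle and distal nephron (0.43, and 0.20, adjusted p 0.0801), nuclear oxidative phosphorylation (0.15, and -0.03, adjusted p 0.632), liver (0.75, and 0.55, adjusted p 0.0584) and immediate early genes (-0.34, and -0.21, adjusted p 0.105). Without CKO IRI 29 they were NRF2 targets (0.19, and 0.01, adjusted p 0.527), cholesterol synthesis (0.27, and 0.10, adjusted p 0.442), glutathione conjugation (0.19, and 0.15, adjusted p 0.0525), immediate early genes (0.0525) and interferon response (-0.22, and -0.15, adjusted p 0.0728). Without WT IRI 24 they were nuclear oxidative phosphorylation, NRF2 targets and immediate early genes (0.0813 each), liver (0.0865) and cholesterol synthesis (0.18). Without WT IRI 49 they were NRF2 targets (0.276), liver (0.0784) and interferon response (0.512), without WT IRI 13 cholesterol synthesis (0.128) and immediate early genes (0.17), and without CKO IRI 7 interferon response (0.111). Among these lists other medians moved over 1.5 times as well. Loop of Henle was 0.73 without CKO IRI 29, 0.71 without WT IRI 49, 0.28 without WT IRI 13 and 0.26 without WT IRI 24. Nuclear oxidative phosphorylation was 0.24 without CKO IRI 29, 0.23 without WT IRI 49 and 0.03 without WT IRI 24. Immediate early genes were at -0.74 without WT IRI 49 and -0.53 without CKO IRI 7. NRF2 targets were at 0.34 without CKO IRI 15, 0.30 without CKO IRI 7, 0.08 without WT IRI 49 and 0.07 without WT IRI 24. Glutathione conjugation was 0.33 without WT IRI 49 and 0.29 without CKO IRI 7. Cholesterol synthesis was 0.16 without WT IRI 24 and 0.13 without WT IRI 13, liver 0.41 without WT IRI 24, and interferon response -0.36 without WT IRI 13 and -0.07 without WT IRI 49. Antioxidant enzymes were not called (0.08, adjusted p = 0.111), with Gpx7 at -0.84 and Cat at 0.71, and none passed, though camera called the list higher without WT IRI 13 (0.18, adjusted p 0.00850) or CKO IRI 7 (0.27, adjusted p 0.0307).

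**Figure D3:**
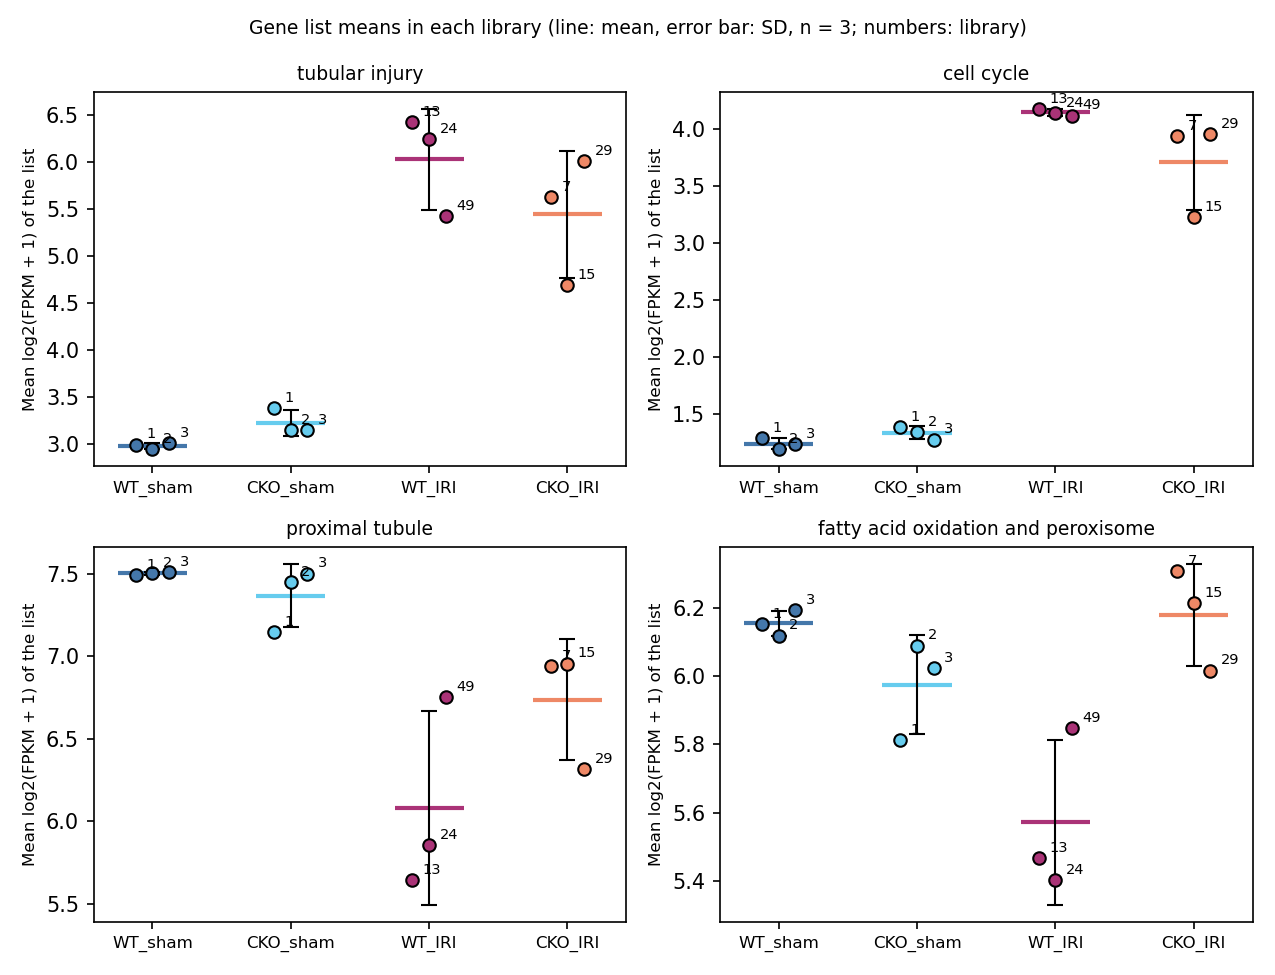
Mean log2(FPKM + 1) of 4 gene lists (vertical axes) in each library by group (horizontal axes), with lines for group means, error bars for SD (n = 3) and library numbers beside the points. Tubular injury and cell cycle means rise and proximal tubule means fall with IRI, and for fatty acid oxidation and peroxisome the CKO IRI libraries (6.02 to 6.31) lie above the WT IRI libraries (5.40 to 5.85).

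The interaction asked whether injury changed genes differently in the libraries labelled CKO. limma called Tmem67 (1.66, SE 0.16, adjusted p = 0.00303) and Pofut2 (-1.69, SE 0.14, adjusted p = 0.00192). Pde4b (1.44), Crybg3 (1.25), Kcnk5 (1.53), Id3 (-1.40), Marcksl1 (-1.65) and Cmtm3 (-1.35) had the next smallest p and did not pass, nor did Gpx3 (1.33, SE 0.51, adjusted p = 0.231). Unadjusted p was under 0.05 for 2233 genes. The count was 579 without WT IRI 49, 6 without WT IRI 24 and 4 without CKO IRI 29. No list member passed over all genes, but adjusted over the list alone 38 of 46 ribosomal protein genes were lower (Rps16 at -0.80), as were 13 of 31 NF-kB and cytokine genes, 11 of 31 interferon response genes and 4 of 30 tubular injury genes, and 15 of 41 fatty acid oxidation and peroxisome genes (Acot12 at 1.34) and 5 of 8 gluconeogenesis genes were higher. Camera called 13 lists, none with an estimated correlation (lowest adjusted p = 0.483).

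The genotype differences in sham and after injury were compared across the 12469 genes, without any shared library. Pearson's r was -0.188 and Spearman's rho -0.21, with a covariance of -0.0252. With 1 library left out r ran from -0.287 (without CKO IRI 15) to -0.077 (without CKO sham 1).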

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

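The test of Gpx3 without WT IRI 49, that of Gpx3 relative to proximal tubule genes (with and without that library) and that of WT IRI 49 on genes not called between IRI and sham were chosen after related results had been seen, the last as a further condition added once the position of 0.246 was known, and the wording of the pattern of switching transcripts was changed after its result, with its bounds kept. A difference between the genotypes in the effect of injury marked the following results. Single genes were Pofut2 (-1.69) and Tmem67 (1.66). Lists with a lower interaction median were ribosomal proteins (-0.595), NF-kB and cytokines (-0.867), interferon response (-0.698), cell cycle (-0.526), tubular injury (-1.045), macrophage and monocyte (-0.585), fibroblast and extracellular matrix (-0.444) and necroptosis and pyroptosis (-0.507). Lists with a higher one were fatty acid oxidation and peroxisome (0.676), proximal tubule (0.77), gluconeogenesis (1.206), cholesterol synthesis (0.549) and loop of Henle and distal nephron (0.405). Chance was not excluded for these counts: of 100 divisions of the libraries between the genotypes, 31 called at least 2 genes (highest other 182) and 45 called at least 13 lists (highest other 19). With 1 library left out, list calls lost were tubular injury without CKO IRI 15 (median -0.469, adjusted p 0.117), loop of Henle and distal nephron without CKO IRI 15 (0.252, adjusted p 0.16), fibroblast and extracellular matrix without any 1 of WT sham 1, CKO sham 1, CKO sham 3, WT IRI 13, WT IRI 49 and CKO IRI 7 (0.0536 to 0.395), and necroptosis and pyroptosis without any 1 of WT sham 2, WT sham 3, CKO sham 1, WT IRI 13, WT IRI 24 and CKO IRI 15 (0.0587 to 0.117). Calls were kept with other medians for cell cycle (-0.336 without CKO IRI 15), cholesterol synthesis (0.352 without CKO sham 1, 0.354 without WT IRI 13), loop of Henle (0.158 without WT IRI 13, 0.661 without WT IRI 49, 0.618 without CKO IRI 29) and fibroblast (-0.817 without WT IRI 24). None of these interaction list calls held in camera with an estimated correlation (lowest adjusted p = 0.483).

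Gpx3 was not lower in the libraries labelled CKO IRI. A wrong genotype label of WT IRI 49 is argued against as the whole cause: without that library the difference was -0.001 (SE 0.20), short of that in sham by 0.813 (SE 0.26), and WT IRI 13 and 24 (2788 and 3568 FPKM) lay within the range of CKO IRI (2779 to 3723 FPKM). The 0.813, the interaction of Gpx3 without WT IRI 49, was not called (limma p 0.0116 unadjusted and 0.0939 adjusted). Whether that library came from a knockout kidney cannot be told apart from a milder injury: on the 1394 genes called without it its median position was 0.246, where 0 is the CKO IRI mean and 1 the WT IRI mean, inside the bound of 0.25 set beforehand for a knockout kidney, with 81% of the genes nearer the CKO IRI mean, 0.099 on the 20 genes of smallest p and no more than 1058 genes called by any other of the 10 divisions of the other 5 libraries, but these genes also follow the severity of injury, and on the 61 of them not called between IRI and sham it was 0.519. Neither explanation accounts for the Gpx3 value of WT IRI 49. At 1075 FPKM it lay below each CKO library (2501 to 3723 FPKM) and below WT IRI 13 and 24, which would be the more injured. Relative to the mean of the proximal tubule list, Gpx3 differed by -0.68 in sham and by -0.138 after IRI (exact permutation p = 0.1 and 1, n = 3 each), but the latter rests on WT IRI 49 (3.32, against 5.80 and 5.95 in the other WT IRI libraries and 4.61 to 5.13 in CKO IRI), without which it was -0.989 (exact permutation p = 0.1, n = 3 and 2). Without WT IRI 49, however, Gpx3 itself differed by -0.001, and 0.1 is the smallest p that 10 divisions allow. The -0.989 thus restates the list means, which were 5.65 and 5.85 in WT IRI 13 and 24 and 6.32 to 6.96 in CKO IRI. Any gene unchanged between these libraries would give such a value, so it cannot decide the question. Loss of proximal tubule transcripts in the other WT IRI libraries stays open.

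Injury changed genes less in the libraries labelled CKO, with a median ratio of 0.579. The ratio of 0.577 after quantile normalization argues against scaling as the whole cause, and the highest ratio with 1 library left out, 0.718 (without CKO IRI 15), against any 1 library as the whole cause. Chance division of unequal injuries may account for it: 2 of the 20 ordered divisions of the 6 IRI libraries gave a ratio as low, the lowest other being 0.511. The division of WT IRI 13, WT IRI 24 and CKO IRI 29 against the rest called 832 genes, against 5 for the genotype labels, which points to a structure of the samples, but without WT IRI 49 the genotype labels called 1394, more than any other division (highest 1058), so that library alone may set these counts. An effect of the knockout on injury stays open as an untested biological explanation.

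Tmem67 was 1 of 6 transcripts below 0.2 FPKM in the 3 libraries of 1 group and at least 2 FPKM in the other libraries, of 68 transcripts that were low in exactly 3 libraries. Chance gives 1.24 of these, fewer than were seen (exact binomial p = 0.00151). That test takes all sets of 3 libraries as equally likely and the transcripts as independent. Transcripts at 0, however, numbered from 1524 in CKO IRI 7 to 2560 in WT IRI 13. Switching of transcript estimates regardless of group therefore stays open. Of the 6, 3 (Arhgef3, Tmem67 and Ddx6) were low in WT IRI.

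Divisions of the other comparisons were too few, 10 each, for a share under 0.05. The real count and the highest of the others were 4608 and 3 genes for IRI in WT (1 division as high), 896 and 8 for IRI in CKO (1), 0 and 4 for CKO against WT in sham (10), and 5 and 832 after IRI (3). For lists they were 17 and 17 (2 divisions as high), 16 and 19 (2), 12 and 14 (3), and 16 and 17 (3). Each other division left the compared groups unequally mixed. Part of a real difference would stay in it, so its count does not measure chance alone.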

How the results depend on the processing

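Single transcripts, genes with no transcript at 0, 1 weight per group and the removal of CKO sham 1 with WT IRI 49 were chosen after seeing the data. The cause of a change was not tested unless given. Counts for IRI in WT stayed within 1.5 times of 4608 except with a log2 threshold of 1 (1821; 489 for IRI in CKO), which is stricter by construction. For IRI in CKO (896) they were 476 with only the groups compared, 3551 with array weights and 435 for transcripts. For sham (0) they were 1 with a pseudocount of 0.1, 2 with no filter, 11 with only the groups compared, 124 with array weights, 1 with no trend, 7 for transcripts, 1 for genes with no transcript at 0, 9 with 1 weight per group and 6 without both libraries. After IRI (5) they were 1 with the filter of 5 FPKM, 0 with only the groups compared, 723 with array weights, 27 for transcripts, 2 for genes with no transcript at 0, 2 with 1 weight per group and 1592 without both libraries. For the interaction (2) they were 1 with the filter of 5 FPKM, 4 with quantile normalization, 841 with array weights, 21 for transcripts, 1 for genes with no transcript at 0 and 148 without both libraries. List calls (74 over the 5 contrasts) were 0 with an estimated correlation and 35 with directional fry. Of the described list calls 10 were lost after quantile normalization, 3 after trimmed-mean scaling and 13 without both libraries. Totals there were 71, 74 and 69, as other lists were called instead. The similarity of the IRI changes was 0.703 as Pearson's r and 0.576 as Spearman's rho, and r was 0.741 without both libraries. For the genotype differences r was -0.188, and -0.059 without both libraries. With 1 library left out, ranges were 3090 to 5227 (IRI in WT), 396 to 1453 (IRI in CKO), 0 to 2 (sham, highest without CKO sham 1), 5 to 1394 (after IRI), 2 to 579 (interaction), 70 to 77 (list calls), 0.637 to 0.76 and -0.287 to -0.077 (similarities). Gpx3 ranged from -0.914 to -0.701 in sham and from -0.001 (without WT IRI 49) to 0.863 after IRI, and it was -0.001 after IRI without both libraries. Its IRI change in CKO ranged from -0.013 to 0.197 and turned to -0.006 without CKO sham 1, to -0.013 without CKO IRI 7 and to -0.006 without both libraries, and mt-Co2 in sham to 0 with quantile normalization. Of the values of named genes under alternatives, 226 of called genes lost the threshold and 307 of others gained it. With the replicate block in the sham groups 0 genes were called and Gpx3 differed by -0.814. Deviations from the group mean correlated at 0.004, -0.031 and -0.002 between same-numbered sham libraries of the 2 genotypes. Between differently numbered ones they correlated at -0.015 to 0.022. No pairing by number was seen, but so few pairs cannot exclude it. The count test was not run because whole reads were not recovered. Read depth is unknown, which limits what can be said of low genes.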

Other observations

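Values of 6 genes with roles in the circadian clock are given here, chosen after they were seen and not as a tested list. Nr1d1 differed by -1.71 (limma adjusted p = 0.000688) in WT and -2.47 (0.000141) in CKO, Dbp by -1.61 (0.0183) and -2.59 (0.00665), and Ciart by -1.27 (0.00178) and -1.24 (0.00627). Cry1 differed by 1.48 (0.00224) and 1.62 (0.00441), and Npas2 by 0.68 (0.00419) and 1.02 (0.0014). Arntl passed in CKO (1.67, adjusted p = 0.00178) and not in WT (0.58, 0.0739), and the interaction was not called for these genes. The hour of tissue collection is not given in the sources used here.

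Genes of ferroptosis, a form of cell death, were not called as a list in any contrast. Their camera adjusted p was 0.281 for IRI in WT, 0.734 for IRI in CKO, 0.982 for CKO against WT in sham, 0.131 after IRI and 0.309 for the interaction. Their list means were nonetheless higher in each library labelled CKO IRI (4.97 to 5.25, log2) than in each labelled WT IRI (4.78 to 4.91). That difference was 0.273, with an exact permutation p of 0.1, the smallest possible. For IRI in WT the difference was -0.227, with the same exact permutation p. Selenoprotein and selenium handling genes were not called either (0.351, 0.423, 0.82, 0.71 and 0.722). Genes next to Gpx3 on chromosome 11, 12 of them tested, were not called in sham (0.82) or after IRI (0.757). Of 10 joint capsule and cartilage markers only 1 was tested, with log2 values of 0.22 to 1.40, beside an extraction protocol that names joint capsule. Of 8 blood genes 5 were tested, and their list mean ran from 2.73 in WT IRI 24 and CKO IRI 7 to 6.33 in WT IRI 49 and 6.72 in CKO sham 1, without separating the genotypes.

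The values of some transcripts switched between libraries without following the groups. A Gapdh transcript was listed at 0 in WT sham 1 and 2, CKO sham 2 and 3, WT IRI 13 and CKO IRI 7 and 15, and at 285 to 448 FPKM in the other libraries, and the main Gpx1 transcript lay between 184 and 276 FPKM in 6 libraries and between 567 and 770 in the others. The other deposited Gpx1 transcript was low in the same 6 libraries (11.6 to 23.0 FPKM, against 65.7 to 283). For Gpx1 the sum per gene, which was tested, therefore does not remove the switch. Transcripts at 0 in a library and at 5 FPKM or more in another of the same group numbered 265 in WT sham, 382 in CKO sham, 570 in WT IRI and 390 in CKO IRI.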
